A study of Mus musculus with 6 samples.

How the data were processed

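RNA was taken from microdissected otic vesicles of mouse embryos at embryonic day 11.5, in 3 pools of Mest-KO and 3 pools of control embryos. Per the labels' protocols, periotic tissue was treated with dispase for 30 min at 37 °C, RNA was isolated with a micro-scale column kit, and biotin-labelled cRNA was made from 300 ng of total RNA and hybridised to Affymetrix mouse arrays. The labels call the 3 arrays of a group biological replicates. Per the submitters' processing notes, Affymetrix Expression Console 1.1 was used. The deposited values are probe set intensities on a linear scale, and the values themselves show that each array was scaled to a trimmed mean of 500, with 2% trimmed from each end. The algorithm that summarised the probes and the background correction are not given in the sources used here, and scaling alone leaves the shapes of the distributions unequal between arrays. The table held no detection calls.

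The table held 45101 probe sets, of which 64 were controls and were left out. The platform annotation gave 1 gene symbol to 34945 probe sets and several to 932, and 9160 others are unnamed here. Symbols were updated through RefSeq gene identifiers for 34741 probe sets. Genes were named only from probe sets with 1 symbol, 18193 genes in all, of which 9010 had more than 1 probe set.

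As fixed before the data were examined for the case of linear values, intensities under 1 were set to 1, log2 was taken, and the arrays were quantile normalized. Each gene was read from its probe set with the highest mean, and genes were kept when that mean lay above the 40th percentile of all probe sets, which was an intensity of 34.4. This left 12462 genes and 27022 probe sets. The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend, no covariate) at a Benjamini-Hochberg adjusted p under 0.05. Tbx1 was tested without the filter and with an exact two-sided permutation test. For 27 gene lists, also fixed before the data were examined, camera was run with a preset correlation of 0.01 and adjusted over the lists. They were repeated with an estimated correlation and with fry. The lists cover the ventral and dorsal vesicle, prosensory and Notch genes, neurogenesis, retinoid, hedgehog, Wnt, FGF and BMP signalling, Hox genes, other cell types of the dissection, and cell states. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

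The rule for named genes took Tbx1, up to 12 genes per direction past the threshold, filled to 5 with the genes of smallest p and a log2 change of at least 0.5 where fewer passed, up to 4 members of each list with a call, the member with the smallest p of each other list, and a fixed set of ear and retinoid genes. Genes named for other reasons are said to be chosen after their values were seen. The steps were tested on simulated data with the levels and spread of this comparison, 12462 genes with 200 changed, in 10 simulations. Without the trend, 70.9% of genes changed 2-fold and 91.6% of genes changed 4-fold were called, with 7.1 false calls per simulation. With the trend the values were 71.7%, 91.3% and 8.4. The 2-fold and 4-fold genes were changed in the same simulations, which eases the adjusted threshold for all of them. These shares therefore do not carry over to data with few changed genes, and a count of 0 does not show that such changes are absent. A list of 20 genes shifted by 0.4 was called in 20 of 20 simulations. There the genes varied independently and all members of the list shifted alike. In the real arrays the estimated correlation was 0.0937 for the FGF list and 0.619 for the mesenchyme list. The simulation therefore does not show how camera does on lists whose members vary together or shift less.

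Alternatives listed in advance were other filters on dim probe sets, median centring, other rules for genes with several probe sets, a floor at 16, a variance trend with and without robust fitting, array weights, the replicate number as a block, leaving out each array, a threshold of 0.10, a plain two-sample statistic, and the other list tests. The deposited scaling without quantile normalization, the trend under each other setting and in camera were added after seeing the data. With an array left out, probe sets and filter were chosen anew from the arrays that remained, and a version that kept those of all 6 arrays was also added after seeing the data. No array was left out of the main results, and no pair of arrays shared more than 1 exactly equal value.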

Results

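Gene expression was measured in the otic vesicle, the epithelial sac that forms the inner ear, of mouse embryos at embryonic day 11.5. In the Mest-KO group, the transcription factor gene Tbx1 had been deleted with T-Cre, a recombinase active in early mesoderm, so the deletion concerned the tissue around the vesicle. The controls were T-Cre conditional heterozygotes. Each group held 3 arrays, and each array held RNA from the left and right ears of 3 pooled embryos of one genotype. The comparison asks how the otic vesicle differs when Tbx1 is lost from the mesoderm around it. The deposited intensities had a trimmed mean of 500 on every array, and the number of arrays limits the precision. Changes are given as Mest-KO minus control in log2 units with the standard error of the limma fit, with n = 3 arrays per group throughout.

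Tbx1 itself was read by 1 probe set. Its intensity was 775 ± 116 (SD, n = 3) in Mest-KO and 785 ± 105 (SD, n = 3) in control. The log2 difference was -0.03 (SE 0.165), with a 95% confidence interval from -0.446 to 0.392, and the exact two-sided permutation p was 1, where 0.1 is the smallest that 3 against 3 arrays allow. Its sign changed when single arrays were left out, over a range from -0.14 to 0.06. The deletion was directed at mesoderm, and the position of the probe set relative to the deleted part is not given in the sources used here, so this value does not check the labels.

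Of the 7 genes with an adjusted p under 0.10, 5 were lower and 2 higher in Mest-KO. Clu, which encodes the secreted chaperone clusterin, had an intensity of 1406 ± 330 (SD) in Mest-KO and 6975 ± 885 (SD) in control, 4.98-fold lower on the normalized scale (log2 difference -2.32, SE 0.212). Itih5, of the family of inter-alpha-trypsin inhibitor heavy chains, differed by -1.21 (SE 0.0942), Plet1, an epithelial surface protein gene, by -1.40 (SE 0.137), and Gata3, a zinc finger transcription factor gene needed for inner ear development, by -1.02 (SE 0.107). Saa1, an acute-phase protein gene, differed by -1.42 (SE 0.133). Gucy1a1, a subunit of soluble guanylate cyclase, was higher by 1.07 (SE 0.108), and Orly, a gene annotated to the Y chromosome, by 0.88 (SE 0.0881). None of these passed the main test: limma, with 1 variance prior for genes of all levels, found 0 of 12462 genes at an adjusted p under 0.05. The smallest adjusted p was 0.0899, and 642 genes had an unadjusted p under 0.05, of which 279 were higher and 363 lower in Mest-KO, against 623 that chance gives. The plain two-sample statistic also gave 0 genes after adjustment. The values of 1322 genes did not overlap between the groups, which is 10.6% of the genes, and chance gives 10%.

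With a prior that follows expression level (limma's trend option, an alternative listed before the data were examined), 13 genes passed the adjusted threshold, 12 of them lower in Mest-KO. Clu (adjusted p = 8.4e-05), Itih5 (0.00022), Plet1 (0.000973), Gata3 (0.000973) and Gucy1a1 (0.00538) were among them, and Gucy1a1 was the gene that was higher. The other 8 were singled out after their values were seen. Slc36a2, an amino acid transporter gene, differed by -2.57, and Fst, which encodes the secreted activin antagonist follistatin, by -1.31. Muc15, a membrane mucin gene, differed by -1.09, Scara3, a scavenger receptor gene, by -0.98, and Car13, a carbonic anhydrase gene, by -0.86. Slc39a8, a zinc transporter gene, differed by -0.65, C1qtnf12 by -0.47 and the imprinted gene Nnat by -0.42. The residual SD fell with level, from a median of 0.466 in the dimmest genes to 0.0843 in the brightest, and the prior carried 2.32 degrees of freedom without the trend and 7.90 with it. In the main fit 7 genes passed at an adjusted p under 0.10, and 7 passed at 0.05 where only genes above the 60th percentile of brightness were tested. Without control replicate 1 the count with the trend was 6, without control replicate 2 it was 7, and without Mest-KO replicate 2 it was 9, or 8 with the probe sets of all 6 arrays kept. With the mean of a gene's probe sets the count was 6, and Plet1 (limma adjusted p = 0.664) and Gucy1a1 lost their calls. With the most variable probe set it was 5, and Itih5 (limma adjusted p = 0.0874), Plet1 and Gucy1a1 were not called.

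**Figure D1:**
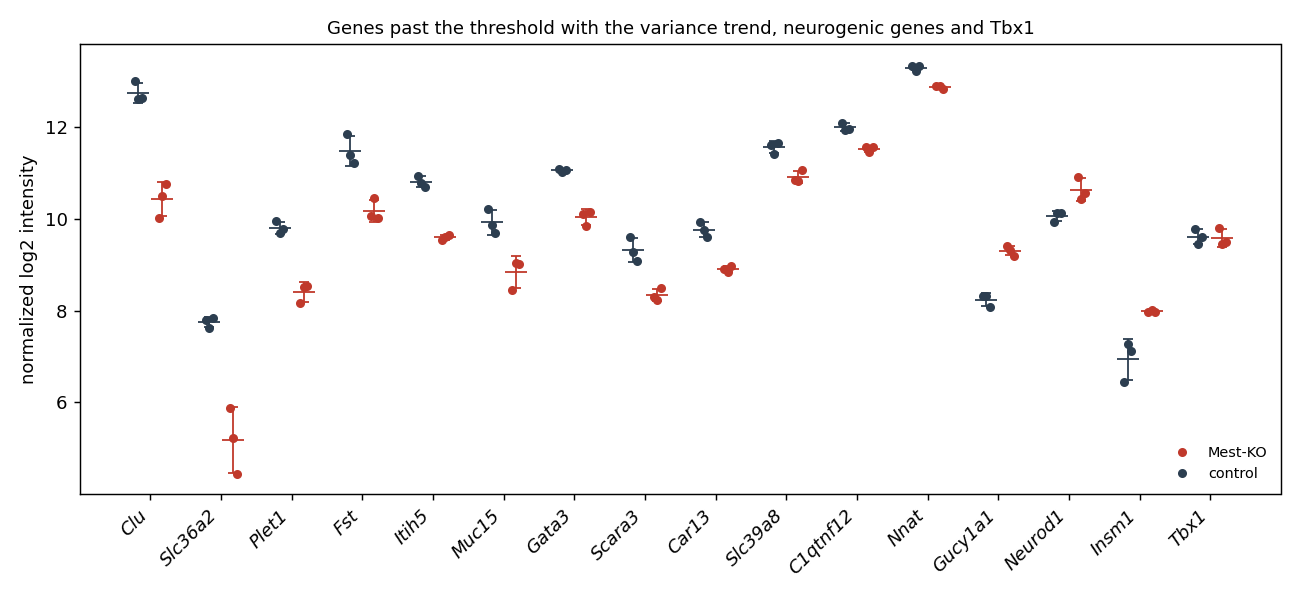
Normalized log2 intensity (vertical axis) of the 13 genes past the threshold with the variance trend, of Neurod1, Insm1 and Tbx1 (horizontal axis), in Mest-KO (red) and control (dark blue). Points are arrays, and bars are the mean and SD of 3 arrays. Clu lies 2.32 lower in Mest-KO and Gucy1a1 1.07 higher, while Tbx1 overlaps between the groups.

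Of the remaining genes taken by the rule for named genes, those with the smallest p among the higher ones were Ssbp4, Sp5 and Igfbp3. Their log2 changes were 0.56, 0.82 and 0.53. The signal of Orly, 46.6 in the control 2 pool, where Eif2s3y stood at 12.1, was close to the 56.9 and 54.5 of the other controls. It thus did not follow the presence of the Y chromosome in these pools, and its change cannot be read as one of a Y transcript. Orly and Ssbp4 had adjusted p of 0.552 and 0.744 with the trend. The adjusted p of Saa1 with the trend was 0.167, and its second probe set, below the filter, differed by -0.23. The probe sets of Clu ran from -2.21 to -2.42, and the other probe sets of Itih5 gave -1.46 and -1.47.

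Among genes of the ventral, cochlear side of the vesicle, 0 of 19 passed over all genes, and 3 passed when adjusted over the list alone. Gata3 was lower (limma, adjusted p over the list alone 0.00103). Gli1, a transcriptional target of hedgehog signalling, was lower by a log2 difference of -0.97 (SE 0.243), and Fgf3 was higher by 0.56 (SE 0.122). Ptch1, the hedgehog receptor, differed by -0.25. Of the ventral genes named in advance, Otx1 differed by 0.15 (SE 0.403), Otx2 by -0.27 (SE 0.141) and Eya1 by -0.08 (SE 0.122), and the signs of Otx1 and Eya1 changed when single arrays were left out. Other probe sets of Eya1, above the filter, gave -0.34 (SE 0.159) and -0.24 (SE 0.452). Pax2 was not analysed here. The list had no call in one direction (camera adjusted p = 0.445), nor had the dorsal, vestibular list (0.532). The dorsal member with the smallest p was Lrig3, with a log2 change of 0.31. With fry's test for change in either direction the adjusted p was 0.00044 for the ventral and 0.0431 for the dorsal list. A few members can carry that test. In the dorsal list none passed when adjusted over the list alone (smallest limma adjusted p 0.234). In the prosensory and Notch list (camera adjusted p = 0.353), Sox2 differed by 0.18 (SE 0.0990).

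Of 25 genes of the neurogenesis and ganglion list, 14 were higher and 11 lower in Mest-KO, and none passed over all genes (camera adjusted p = 0.216). The mean of the list ran from -0.0659 to 0.176 with an array left out. Insm1 had an intensity of 258 ± 3.94 (SD) in Mest-KO and 122 ± 31.2 (SD) in control, a log2 difference of 1.04 (SE 0.217), and its second probe set gave 0.44. Neurod1 was higher by 0.57 (SE 0.144), with 0.70 at its second probe set, and Elavl3 by 0.38 (SE 0.121). Neurog1 differed by 0.33 (SE 0.173), with values that overlapped between the groups. Adjusted over the list alone, Insm1 and Mapt passed (both 0.0331) and Neurod1 had 0.0546, while with the trend Insm1 and Neurod1 passed (both 0.00764) and Mapt had 0.227. Mapt, a neuronal microtubule protein gene, was lower by -0.97, but it was dim. Its other probe sets, all below the filter, gave 0.35, 0.15 and -0.72.

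With the preset correlation, camera called the FGF signalling list as shifted upward, with 14 of 19 genes higher in Mest-KO (adjusted p = 0.00872, mean log2 change 0.12, median 0.16). The call was lost with an estimated correlation (camera adjusted p = 0.531). The list mean was 9.16, 9.24 and 9.01 on the Mest-KO arrays and 9.05, 9.01 and 8.98 on the controls. Mest-KO 3 thus lay within the range of the controls, and the SE of the mean change over arrays was 0.0698. None of the members of the list passed over all genes or adjusted over the list alone, and 4 had an unadjusted p under 0.05. These were Fgf3, a ligand, at 0.56, Il17rd, an FGF feedback inhibitor gene, at 0.29, Spry4, another inhibitor gene, at 0.75 (SE 0.269), and Etv4, a transcription factor gene downstream of FGF signals, at 0.24. The call was also lost with the mean of all probe sets of a gene (mean -0.02) and with the most variable probe set (mean -0.05). Without Mest-KO replicate 2 it was lost where each gene's probe set was chosen anew from the arrays that remained (adjusted p of 0.0967, mean 0.05), and it passed where the probe sets of all 6 arrays were kept (adjusted p of 0.0450, mean 0.07). The count of lists past the threshold, with probe sets chosen anew, was 3 without Mest-KO 1 or Mest-KO 3, and 2 without Mest-KO 2, control 1 or control 3. With probe sets kept it was 4 without Mest-KO 1, 5 without Mest-KO 2, and 2 without Mest-KO 3, control 1 or control 3. Other probe sets of Etv4 and Il17rd gave -0.54 and -0.26. A second probe set of Spry4, of nearly the same brightness (mean log2 6.84 against 6.86), gave 0.17 (SE 0.305) over all arrays. Without Mest-KO replicate 2 Spry4 stood at 0.49 on the probe set used here and at -0.02 on the one chosen anew.

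Of the other signalling lists, none passed with camera. Retinoid metabolism and receptor genes lay lower on balance, 12 of 15 (adjusted p = 0.0851), with Rxrg, a retinoid X receptor gene, at -0.67 (SE 0.165). Cyp26a1 and Cyp26b1, which encode enzymes that degrade retinoic acid, differed by -0.11 (SE 0.123) and 0.17 (SE 0.168), and Cyp26c1 was not analysed here. The receptor gene Rarb differed by -0.09 (SE 0.178), with a sign that changed when single arrays were left out. Genes responsive to retinoic acid did not shift (0.771), with Stra6 at -0.18, and their test and median lay below 0 while their mean lay above it. BMP signalling genes were lower in 13 of 17 cases (0.113), with Smad6 at -0.58, or -0.33 without control replicate 2. The hedgehog list (0.506) had 5 genes higher and 6 lower, and Gli1 and Ptch1, both lower, had adjusted p over this list alone of 0.0705 and 0.174, and of 0.0321 and 0.0375 with the trend. In the Wnt list (0.665), Sp5 passed when adjusted over the list alone (limma adjusted p 0.0169). In the same list Lgr5 differed by -0.60 (-0.15 at its second probe set), Dkk3 by -0.31 and Wnt7a by -0.43. Hox genes gave 0.966, with Hoxc4 at -1.19 (SE 0.527), and their mean lay below 0 while the median and the test lay above it. With fry's test for change in either direction, 6 of the 27 lists passed, which were the ventral, dorsal, FGF, hedgehog, chondrogenic and retinoid metabolism lists, and with its test for one direction 0 did. The test for either direction was not repeated on regrouped arrays, so these passes do not show that whole lists changed.

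Lists of the other cell types that a dissection can hold gave no call. Neural crest and glia had an adjusted p of 0.0851 with Cdh6 at 0.69, and endothelium 0.0953 with Flt1 at 0.69. The mean of the endothelial list ran from -0.0233 to 0.398 with an array left out. Periotic and other mesenchyme gave 0.445, with Snai2 at 0.56 and Pou3f4, a gene of the periotic mesenchyme, at -0.43 (SE 0.763). Otic and other epithelium gave 0.216 with Krt8 at -0.20, macrophages and leukocytes 0.257 with Fcer1g at -0.86, red blood cells 0.697 with Klf1 at -0.34, and hindbrain 0.722 with Lhx1 at -0.67 (-0.04 at its second probe set). Skeletal and cardiac muscle gave 0.492 with Msc at 0.27, and surface and pharyngeal epithelium 0.626 with Pax9 at -0.42 (0.10 at its second). The chondrogenic list of the otic capsule gave 0.697 with Col11a2 at -0.40, and its median lay above 0 while mean and test lay below it. Among lists of cell state, extracellular matrix gave 0.0851 with Fbln2 at 0.68, and its mean ran from -0.0142 to 0.162 with an array left out. Hypoxia and glycolysis gave 0.0851 with Vegfa at 0.61, while another probe set of Vegfa gave -0.15. With an estimated correlation the unadjusted p of these lists were 0.298 and 0.368. The cell cycle list gave 0.722 with Ccna2 at 0.21 (-0.11 at its second probe set), p53 and apoptosis 0.353 with Trp53inp1 at 0.26 (-0.04 at its second), and immediate early and heat shock genes 0.365 with Hspa1b at 0.91. The sex-linked list gave 0.353, with Kdm5d at 2.54 (SE 1.53), or 0.62 without control replicate 2, and with 0.46 and 1.26 at its other probe sets.

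**Figure D2:**
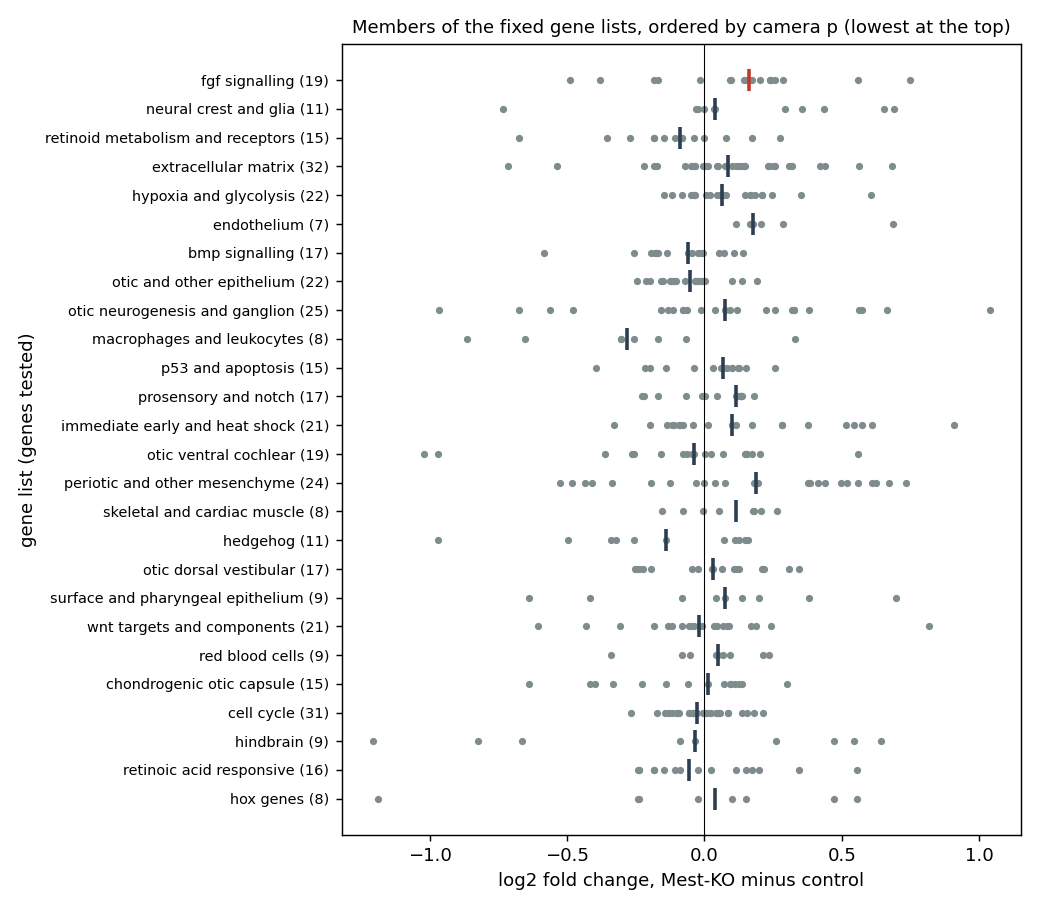
Log2 fold change of Mest-KO minus control (horizontal axis) for each tested member (gray points) of 26 gene lists (vertical axis, with the number of genes tested), ordered by camera p. Vertical ticks are medians, red for the list past the adjusted threshold. FGF signalling has its median at 0.16, and the sex-linked list is not drawn.

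With each probe set tested by itself, probe sets without a gene name included, limma called 0 of 27022 at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 1075, against 1351 that chance gives, and 1 passed at an adjusted p under 0.10. It reads Rorb, a nuclear receptor gene singled out after its values were seen, and lay lower in Mest-KO by a log2 difference of -1.78 (SE 0.110). In the gene fit, which read each gene from its probe set with the highest mean, Rorb was not among the 7 genes with an adjusted p under 0.10.

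The pools also differed within each group. Xist, expressed from the inactive X chromosome of females, had an intensity of 16.1 in the Mest-KO 1 pool and from 2331 to 5034 in the others. Eif2s3y, a gene of the Y chromosome, had 12.1 in the control 2 pool and from 1373 to 2663 in the others. These pools of one sex lean the comparison the same way, toward males in Mest-KO and females in control. The mean log2 level of the mesenchyme list ranged from 7.20 to 8.43 over the Mest-KO arrays and from 7.11 to 8.06 over the controls. Mest-KO 3 lay apart on the first principal component, which held 33.1% of the variance, at 36.4 against -10.3 to -1.77 for the other arrays. Its median intensity was 91.0, against 62.1 to 71.0. Without that array the main count stayed at 0 genes, and the count with the trend was 17.

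**Figure D3:**
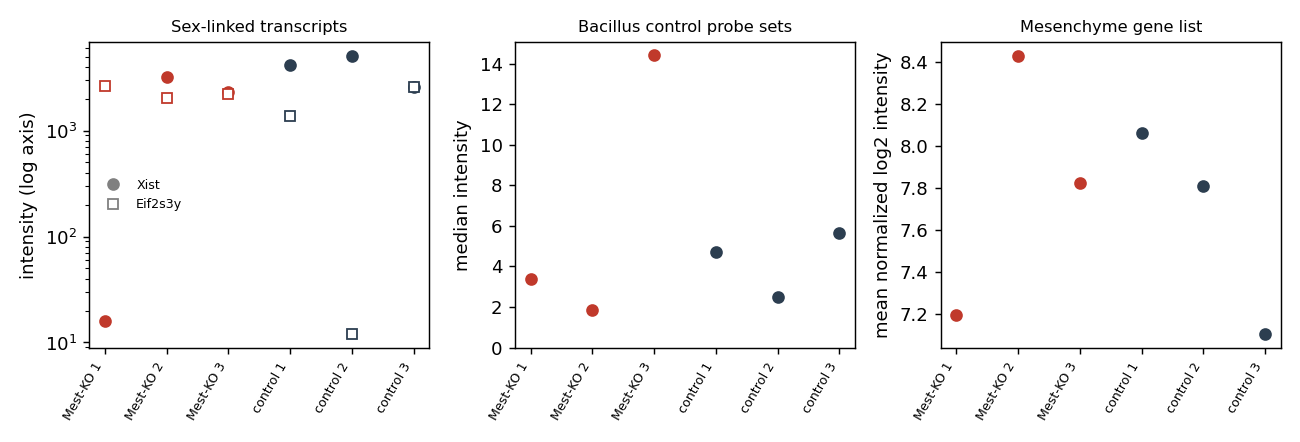
Values per array (horizontal axis) in Mest-KO (red) and control (dark blue). Left, intensity of Xist (filled circles) and Eif2s3y (open squares) on a log axis. Middle, median intensity of 27 Bacillus control probe sets. Right, mean normalized log2 intensity of the mesenchyme list. Mest-KO 1 has an Xist intensity of 16.1 and control 2 an Eif2s3y intensity of 12.1.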

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

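This check was chosen after the values had been seen. The 27 probe sets for Bacillus transcripts, which are controls and enter no comparison, had a median intensity of 14.4 on the array Mest-KO 3. That is above the control arrays, whose highest median was 5.62, and above Mest-KO 1 and 2, at 3.38 and 1.85. On the same array 18.6% of the probe sets lay under an intensity of 16, against 23.5% to 26.9% on the others.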

How the results depend on the processing

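The alternatives with the deposited scaling alone, with the trend under other settings and with an array left out while the probe sets and filter of all 6 arrays were kept were chosen after seeing the data, and the cause of the differences below was not tested unless stated. The count of genes, 0 in the main fit, was 7 with the filter at the 60th percentile, which tests fewer genes, 3 with median centring (Clu, Itih5 and Slc36a2), 1 with the most variable probe set (Rorb), 13 with the trend, 16 with the trend and robust fitting, 7 at a threshold of 0.10, and 92 at an unadjusted p under 0.05 with a fold of at least 1.5. It was 0 without a filter, with the deposited scaling, a floor at 16, the mean of probe sets, array weights, each array left out, and the adjusted plain statistic. With the trend, 6 genes passed with the mean of probe sets, 5 with the most variable probe set, 6 to 17 with an array left out and 7 between the pools that held both sexes. Clu and Gata3 were called with the trend under each of these settings, and Fst in all but the last. The count of probe sets was 1 without a filter, a dim probe set of Map3k21. The count of lists was 5 with the filter at the 60th percentile, 7 with median centring, 2 with the mean of probe sets, 1 to 5 with an array left out (1 to 3 with probe sets chosen anew), 0 with an estimated correlation and 0 with fry.

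The replicate numbers shared between the groups did not pair the arrays: deviations of arrays with the same number correlated at -0.109, -0.00829 and -0.00734. With the replicate block 0 genes, 0 probe sets and 1 list passed, and 8 genes with the trend, all 8 among the 13.

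Over 71 named genes, 1531 of 1587 values kept their sign and side of the threshold, 39 newly passed and 17 changed sign. Over the lists, 527 of 616 values kept both, 31 newly passed, 3 no longer passed and 55 changed direction in camera, which can change while the mean keeps its sign. The list means that follow are those of such changes. Without a filter, the mean of retinoic acid responsive genes was 0.124 and of Hox genes -0.164. At the 60th percentile, Hox genes gave -0.0541, hedgehog -0.0125, Wnt 0.0372 and chondrogenic genes 0.0398. With median centring hindbrain gave -0.0140. With the mean of probe sets, retinoic acid responsive genes gave 0.0395, hindbrain 0.183, cell cycle 0.0297 and Etv4 -0.15. With the most variable probe set, prosensory genes gave -0.0884, hindbrain 0.308, cell cycle 0.0197, Etv4 -0.54, Il17rd -0.26 and Trp53inp1 -0.0396. With the trend, alone or with robust fitting, the mean of Hox genes stayed at -0.0517 as without it, and camera's direction changed.

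With an array left out, with probe sets chosen anew or kept, values ran from -0.14 to 0.0585 for Tbx1, -0.148 to 0.0293 for Eya1, -0.102 to 0.547 for Otx1, -1.01 to 0.489 for Pou3f4, -0.244 to 0.0420 for Rarb and -0.0195 to 0.982 for Spry4. The -0.0195 came without Mest-KO replicate 2 together with a change to another probe set of Spry4, and on the probe set used here Spry4 ran from 0.489 to 0.982. Another 14 named genes, none past the threshold, moved by over 1.5 times with the sign kept. They ran from -0.215 to -0.0200 for Cyp26a1, 0.0426 to 0.295 for Cyp26b1, -1.16 to -0.557 for Fcer1g, -1.75 to -0.770 for Hoxc4, 0.619 to 3.55 for Kdm5d, -0.480 to -0.187 for Klf1, -0.800 to -0.433 for Lhx1, 0.142 to 0.357 for Msc, 0.186 to 0.443 for Neurog1, -0.371 to -0.173 for Otx2, -0.692 to -0.186 for Pax9, -0.744 to -0.329 for Smad6, 0.109 to 0.248 for Sox2 and -0.630 to -0.250 for Wnt7a. List means ran from -0.0397 to 0.00789 for cell cycle, -0.370 to 0.246 for hindbrain, -0.264 to 0.210 for Hox genes, 0.00283 to 0.277 for immediate early genes, -0.692 to 0.0481 for macrophages, -0.0742 to 0.0539 for p53, -0.146 to 0.464 for mesenchyme, -0.0568 to 0.141 for red blood cells, -0.0922 to 0.116 for retinoic acid responsive genes, -0.0486 to 0.186 for muscle, -0.0645 to 0.0311 for Wnt and -0.181 to 0.178 for surface epithelium. Means that crossed 0 while camera kept its direction ran from -0.0233 to 0.398 for endothelium, -0.0142 to 0.162 for matrix, -0.0659 to 0.176 for neurogenesis, -0.00653 to 0.0350 for dorsal genes, -0.000506 to 0.0648 for prosensory genes and -0.309 to 2.06 for sex-linked genes. Dim genes varied most between arrays, and without detection calls the signal over background of single genes is unknown.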

Other observations

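Some genes not described above stood next to the threshold with the trend. They were singled out after their values were seen, with adjusted p from 0.05 to 0.10 in that fit, and none passed in the main fit. Tac1, which encodes the precursor of the neuropeptide substance P, was lower in Mest-KO by a log2 difference of -2.91 (SE 0.649), and its second probe set, below the filter, gave -0.14. Kcnab1, a potassium channel subunit gene, differed by -1.94 (SE 0.288), with -1.65 at its second probe set below the filter. Wdr66 differed by -2.29 (SE 0.456), while its other probe sets, below the filter, gave -0.54, 0.30 and 1.64. Insyn2a differed by -1.14 (SE 0.142), with -0.03 and, below the filter, -1.41 at its other probe sets, 4930481B07Rik by -0.94, Moxd1 by -0.61 and Ccdc80 by -0.62, with -0.64 at its second probe set. Sema3e, a secreted guidance protein gene, differed by -0.56, while its other probe sets gave 0.05, -0.36 and -0.17. Crym, a thyroid hormone binding protein gene, was higher by 0.45 and Slc25a24 by 0.44, with 0.09 at its second probe set.

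The tests of the 3 patterns that follow, and the count of splits for the trend, were chosen after the results were seen. The splits for the main counts were planned. The 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05. For the main count of genes the real split gave 0 and the highest other 0, with 10 of 10 splits as large, and for probe sets again 0 and 0, with 10 of 10. For lists the real split gave 1 and the highest other 6, with 9 splits as large. For genes with the trend the real split gave 13 and the highest other 1, with 1 split as large.

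Of the 13 genes past the threshold with the trend, 10 also passed without Mest-KO 3 and 5 (Clu, Gata3, Itih5, Plet1 and Slc36a2) between the pools that held both sexes, so those calls do not rest on that array or on the pools of one sex. The calls of the other 3 and 8 genes ended with fewer arrays. The SE grew for all 3, and for 7 of the 8. For Muc15 between the pools that held both sexes it was 0.174, against 0.176 over all arrays, and its change was smaller, -0.91 against -1.09. Without Mest-KO 3 the median size of the 3 was 0.49 (median SE 0.0890), against 0.47 (0.0763) with it, with C1qtnf12 at -0.49, Muc15 at -1.18 and Nnat at -0.41. Between the pools that held both sexes the median size of the 8 was 0.88 (median SE 0.162), against 0.92 (0.122) over all arrays. All 13 genes were selected on the same arrays for changes that were large against their spread. Such changes could hardly shrink with arrays left out, so the median sizes leave both explanations open for the 3 and 8 genes. They also say nothing on chance. The pools that held both sexes may still differ in the share of each sex, as Xist stood at 2331 in Mest-KO 3 and 4118 in control 1. For 7 of the genes, 13 of 13 other probe sets above the filter changed in the same direction, which argues against an odd probe set for these. The one-sided exact binomial p of 0.000122 is too small, because probe sets of one gene on the same RNA are not independent. The other 6 genes, Gata3, Gucy1a1, Muc15, Nnat, Scara3 and Slc36a2, had no other probe set above the filter, so an odd probe set stays open for them. Of these, Gucy1a1 had 2 below the filter, at 1.58 (SE 0.441) and 1.01 (SE 0.504), in the same direction but too dim to settle it. The loss of Tbx1 in the mesoderm may account for these changes, as a hypothesis that these arrays do not test by themselves.

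Insm1, Neurod1 and Neurog1 differed by 1.04, 0.57 and 0.33, none past the threshold over all genes, and Neurog1 overlapped between the groups. More ganglion neurons in these dissections could give such values. The mean of 11 genes of differentiated neurons, from a list written after the values of most of them had been seen, differed by -0.27 (SE 0.293). That is below the 0.57 of Neurod1 by more than 2 SE. The array means were 7.88, 8.25 and 7.40 in Mest-KO and 8.37, 7.83 and 8.14 in control, so the low mean leaned on Mest-KO 3. In the whole neurogenesis and ganglion list 14 genes were higher and 11 lower, with Pou4f1 at 0.67 and Nefl at -0.67. The choice of genes could thus set the outcome, and more ganglion neurons stay open as an explanation. Without Mest-KO 3 the median change of the 3 genes was 0.61, against 0.57 with it, so this change did not rest on that array alone. The 3 genes were grouped after their values on the same arrays were seen, so this is no independent test of that array as a cause. A larger number of neuroblasts in the vesicle remains a hypothesis with no test here.

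The upward shift of the FGF list may come from members that vary together from array to array. With the correlation between members estimated at 0.0937, the unadjusted camera p was 0.0756. The array Mest-KO 3 itself did not show the shift, as its list mean of 9.01 lay within the 8.98 to 9.05 of the controls. Without it the mean over the same probe sets was 0.19 (0.16 with probe sets chosen anew), against 0.12 with it. That rise had to follow, as this array had the lowest list mean of the Mest-KO arrays, so it is no separate test. Without Mest-KO 2 the mean over the same probe sets was 0.07 (0.05 with probe sets chosen anew). An effect of the genotype on FGF signalling stays open and untested.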
